A study of Mus musculus with 14 samples.

How the data were processed

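Single-cell RNA-seq libraries were made from sorted lung cells of Ms4a3-tdTomato mice, in which tomato fluorescence marks cells descended from Ms4a3-expressing granulocyte-monocyte progenitors of the bone marrow. Per the labels' protocols, the lungs were perfused and dissociated with enzymes, red cells were lysed, and about 12000 viable cells per sample were loaded on a 10x Genomics droplet instrument. The matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors deposited without normalization. Cell Ranger, Scanpy 1.9.6 and the mouse build GRCm38 (mm10) are named per the submitters' processing notes; the version of Cell Ranger and the authors' cell filters are not given in the sources used here. Gene positions were taken from a GENCODE annotation of GRCm38. All 14 matrices have 31053 gene entries, and every library was assigned to its group from its labels.

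Barcodes with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs were kept. The library of tomato-negative myeloid cells from smoke-exposed mice after rest holds 28010 barcodes, against about 12000 cells loaded, and the lowest UMI count in the 4-week smoke library is 1023. Doublets were scored with Scrublet in Scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes, at most 12%. Its automatic threshold was not used in 9 of 14 libraries, where it marked under 0.5% or over 20% of cells; the top-scoring expected share was marked there. Marked doublets were between 0.886% and 13.8% of a library and were left out of all values except total and median UMIs, leading genes and raised markers of libraries and clusters. The 94875 kept cells were log-normalized to 10000 UMIs and clustered together without batch integration, from 2000 variable genes and 30 principal components, with 15 neighbours and Leiden resolution 1.0. The 41 clusters were named "X-like" from marker lists fixed in advance for alveolar macrophages (AMs), interstitial macrophages, classical and nonclassical monocytes, neutrophils, dendritic cell (DC) subsets, lymphocytes and structural cells. Names were given after the clusters were seen. A cluster led by Inhba and Gpnmb had 0 AM, 7 interstitial macrophage, 3 cDC2 and 1 classical monocyte markers raised over other cells but none among its 10 leading genes, and stayed unnamed. Cluster 23, led by cell cycle genes, had 16 AM markers raised and also 0 among its 10 leading genes. Clusters 7, 8, 9 and 23 make up the AM-like class.

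Counts were summed over the AM-like cells of each library. The 8 libraries sorted by tomato were fitted together with edgeR 4.0.16 (TMM factors, filterByExpr, robust quasi-likelihood test) in R 4.3.3, with a term for each of the 4 exposure groups and a term for tomato, which leaves 3 residual degrees of freedom. The contrasts were smoke against room air at 12 weeks, smoke against room air after rest, the difference between those, and tomato-positive against tomato-negative. P-values were adjusted by the Benjamini-Hochberg method over 5535 genes and called at 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 0.216. The same fit was run on classes with at least 30 cells in each of these libraries, which held for classical and nonclassical monocyte-like cells. The labels do not say how many mice made up a library or whether tomato-negative and tomato-positive cells came from the same mice, so p-values measure only the spread between these libraries.

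Gene lists fixed in advance covered AM identity, monocyte-derived macrophages, lipid-laden macrophages, aryl hydrocarbon receptor targets, the NRF2 antioxidant response, metallothioneins, iron handling, cholesterol synthesis, cholesterol efflux with LXR targets, fatty acid and PPARγ targets, matrix proteases, chemokines, inflammatory mediators, interferon response, MHC class II, complement, lysosome, scavenger and Fc receptors, cell cycle, glycolysis and hypoxia, mitochondrial respiration, and immediate early genes that dissociation can induce. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation.

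The 4-week libraries and the AM-gate libraries after rest were compared 1 against 1 with no test. Values are UMI counts scaled to the library total (CPM) with exact Poisson intervals, log2 ratios of CPM + 5, and the percentile of a list's median among 10000 random lists matched on expression. Cell shares have exact Clopper-Pearson 95% intervals. A gene with 0 counts on a side is given as a bound against 3 counts over that group. All of these intervals and bounds cover counting error only.

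Named genes are the 12 called genes with the largest rise and the 12 with the largest fall in each contrast, at a mean CPM of at least 30 and the same direction in each tomato fraction (in each of the 4 pairs for the tomato contrast). Between single libraries they are the 12 largest log2 ratios each way at a CPM of at least 50. Markers of other cell classes, clone-named, ribosomal and mitochondrial genes were excluded. From each list, up to 4 members with the largest changes are named. Some genes that meet these rules are not reported here. Groups, tests, lists, the naming rule and the main alternatives were fixed before the data were examined.

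The steps were tested on simulated data with 200 genes changed by 2-, 4- or 8-fold. All simulated libraries were drawn from a single pooled profile with independent spread. They do not differ in cluster makeup or captured RNA as the real libraries do, so the false-call rates hold for that setting alone. In the AM-like fit, 11.9%, 80.6% and 90.9% of changed genes were recovered for smoke at 12 weeks, with 3.2% false calls over 5659 genes. After rest 13.4%, 65.7% and 89.4% were recovered with 5.1% false calls over 5582 genes, and for tomato 47.8%, 91% and 98.5% with 5.4% false calls over 5429 genes. Classical monocyte-like cells gave 17.9%, 79.1% and 98.5% for smoke at 12 weeks with 7.8% false calls over 9529 genes. In the 1-against-1 step a lysosome list raised 4-fold came out at a median log2 ratio of 1.94, over 16177 genes.

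Alternatives were DESeq2 1.42.0, scaling by library size alone, other count and cell filters, doublets kept, the proliferating AM-like cluster left out, AM-gate libraries added to the fit, each library left out in turn, other pseudocounts, and subtraction of free RNA. Subtraction of an NK cell profile, the fit without the AM-like cluster of low UMI counts, fits of 4 libraries and shares with the Inhba-Gpnmb cluster counted as AM-like were added after the data were seen. The fits of 4 libraries take the tomato-negative and tomato-positive library of an exposure as its replicates. Their counts of called genes rest on the spread between those few libraries alone.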

Results

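Sorted lung leukocytes of Ms4a3-tdTomato fate-mapping mice were profiled in 14 droplet single-cell RNA-seq libraries. Mice breathed room air (RA) or cigarette smoke (CS) for 4 weeks, for 12 weeks, or for 12 weeks followed by 8 weeks of rest. Of these libraries, 10 came from a myeloid gate of viable CD45+ cells without cells negative for both CD11c and CD11b, and 4, all after rest, came from an AM gate of CD45+CD11c+SiglecF+ cells. Tomato-negative and tomato-positive cells were sorted apart at 12 weeks and after rest, and the 4-week libraries hold both. Each group is a single library (n = 1).

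Total UMI counts at 4 weeks were 61821146 in CS and 62687729 in RA. At 12 weeks they were 41241551 and 20554273 in tomato-negative and tomato-positive CS, and 41752994 and 16821930 in RA. After rest the myeloid gate gave 87565236 and 39653057 in CS and 51770331 and 15601857 in RA, and the AM gate gave 94373709 and 31818073 in CS and 11389241 and 5887899 in RA. Median UMIs per kept cell ranged from 1895 in tomato-positive AM-gate CS to 44137 in tomato-negative AM-gate RA. In the 8 libraries of the model the AM-like class held 21 tomato-negative and 22 tomato-positive cells in CS at 12 weeks against 485 and 80 in RA, and 50 and 121 in CS after rest against 98 and 7 in RA.

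The first comparison asked how smoke changed the makeup of the myeloid gate. AM-like cells made up 0.55% of cells in CS at 4 weeks (95% exact interval 0.42 to 0.707) and 14% in RA (13.2 to 14.7), a 25.4-fold lower share. At 12 weeks they made up 0.452% in tomato-negative CS (0.28 to 0.69) against 8.06% in RA (7.38 to 8.78), and 0.983% in tomato-positive CS (0.617 to 1.49) against 4.47% in RA (3.56 to 5.53). After rest the tomato-negative share was 0.204% in CS (0.151 to 0.269) and 1.02% in RA (0.828 to 1.24), whereas the tomato-positive share was 1.51% in CS (1.25 to 1.80) and 0.547% in RA (0.22 to 1.12). Migratory DC-like cells, named from Ccr7 and Fscn1, made up 8.74% in CS and 0.369% in RA at 4 weeks, 4.33% and 0.648% in tomato-negative cells at 12 weeks, and 0.97% and 0.437% after rest. Interstitial macrophage-like cells, named from the complement genes C1qa, C1qb and C1qc, made up 2.95% in CS and 0.739% in RA at 4 weeks, 3.21% and 1.58% in tomato-negative cells at 12 weeks, but 0.734% and 1.45% after rest. Their tomato-positive shares were 3.31% in CS against 0.838% in RA at 12 weeks and 1.30% against 0.547% after rest.

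An unnamed cluster whose leading genes were Inhba, Gpnmb, Chchd10, Ccl7, Syngr1, Anpep, Mmp14 and Fabp5 made up 51.7% of the 4-week CS library and 0.52% of RA. Its share at 12 weeks was 4.07% in tomato-negative CS against 0.282% in RA and 18.6% in tomato-positive CS against 0.615% in RA. After rest it was 0.489% against 0.312% and 0.923% against 0 of 1279 RA cells. In the AM gate it was 1.48% and 4.55% in CS against 0 cells in RA. Counted as AM-like, this cluster turns the 4-week difference between CS and RA from -13.42 to 37.78 percentage points and the 12-week tomato-positive difference from -3.49 to 14.5. NK cell-like cells, which the gate retains, were 7.22% in CS and 42.2% in RA at 4 weeks. They were 62.0% and 66.7% in the tomato-negative libraries at 12 weeks and 72.2% and 75.3% after rest, and under 0.23% in every tomato-positive myeloid library. Classical monocyte-like cells made up 4.86% in CS and 19% in RA at 4 weeks, and in the tomato-positive libraries 19.9% and 31.2% at 12 weeks and 40.5% and 36.4% after rest. These shares follow what the gate admits and have no replicate check.

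**Figure D1:**
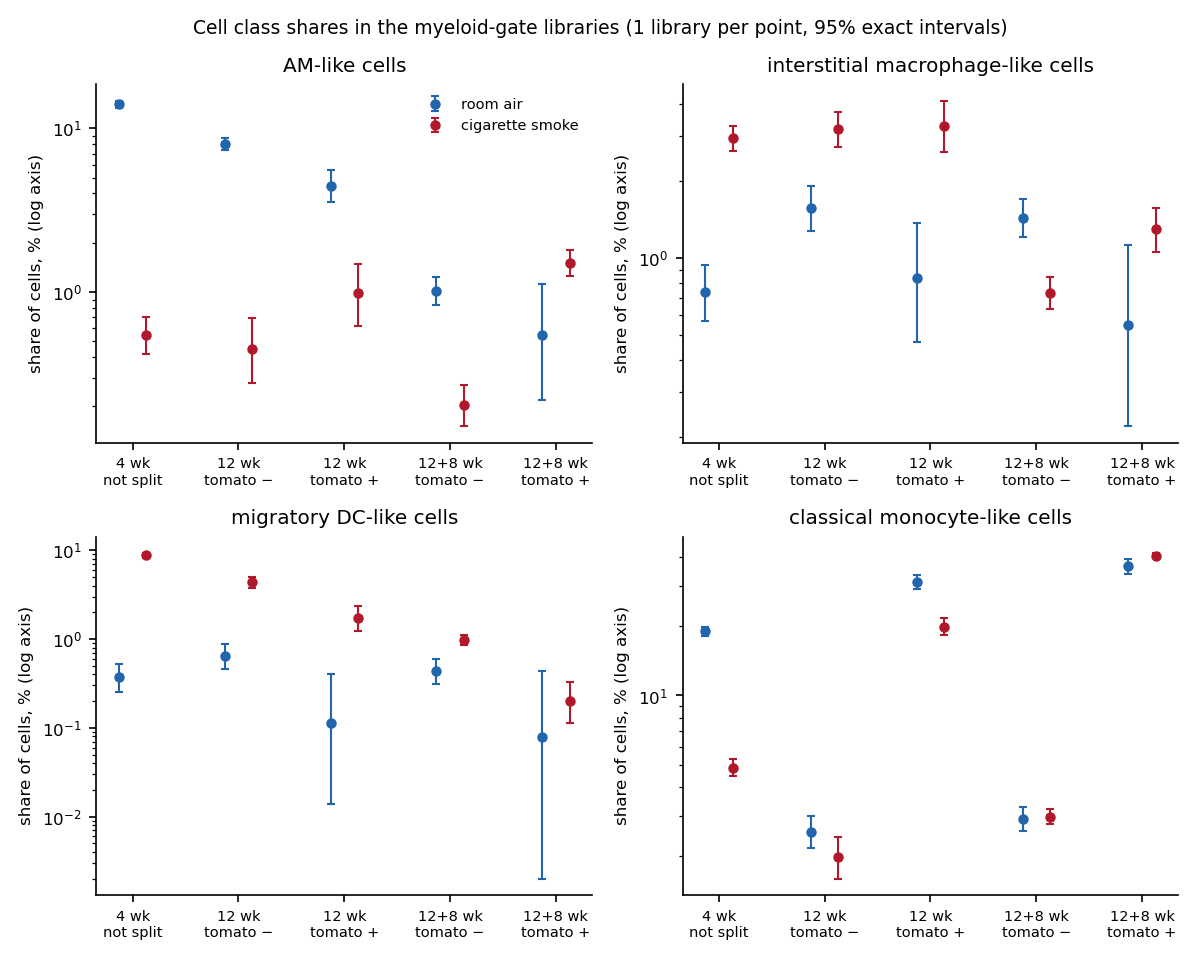
Percent of singlet cells (log axis) that were AM-like, interstitial macrophage-like, migratory DC-like and classical monocyte-like in the 5 myeloid-gate pairs of RA (blue) and CS (red) libraries, with exact 95% intervals for counting error. AM-like shares lay below RA in CS in 4 pairs and above it in tomato-positive cells after rest, at 1.51% against 0.547%.

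The second comparison asked what distinguished AM-like cells during smoke exposure, in the 12-week CS against RA libraries (2 against 2, tomato-negative and tomato-positive). Among the called genes, some that attract monocytes or take up particles and dying cells rose, and some that mark lung-resident AMs fell, though the scavenger receptor list as a whole was not called. Wfdc17, a secreted whey acidic protein family member, rose by 5.51 ± 0.37 log2 units (SE; edgeR adjusted p = 1.29e-07). Msr1, the class A scavenger receptor, rose by 4.35 ± 0.47 (edgeR adjusted p = 2.55e-05). Spp1, which encodes osteopontin, rose by 3.22 ± 0.32 (edgeR adjusted p = 7.11e-06). Fabp1, a fatty acid-binding protein of AMs, changed by -3.88 ± 0.50 (edgeR adjusted p = 0.000167).

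Of 5535 genes tested, 58 rose and 39 fell, and 96 of the 97 went the same way in both tomato fractions. Ccl7, a monocyte-attracting chemokine, rose by 7.01 ± 0.58 (edgeR adjusted p = 1.02e-06), and its neighbour Ccl2 by 4.33 ± 0.64 (edgeR adjusted p = 0.00503). Ccl7 stood at 782.5 CPM in tomato-negative CS, 5.5 in tomato-positive CS, 6.0 in tomato-negative RA and 0.0 in tomato-positive RA. Syngr1, a vesicle membrane protein, rose by 5.99 ± 0.58 and Cd93, a receptor linked to the clearance of dying cells, by 4.79 ± 0.39 (edgeR adjusted p = 7.11e-06 and 1.02e-06). Ccl7 and Syngr1 are also leading genes of the Inhba-Gpnmb cluster, which these values leave out. Mfge8, which bridges dying cells to phagocytes, rose by 3.80 ± 0.41, Igf1, an insulin-like growth factor, by 3.67 ± 0.36, and Itgam, the CD11b integrin chain, by 3.28 ± 0.69 (edgeR adjusted p = 2.55e-05, 7.11e-06 and 0.0167). AA467197 rose by 4.79 ± 0.44 and Basp1 by 3.1 ± 0.38 (edgeR adjusted p = 6e-06 and 0.000106). Ereg, an EGF receptor ligand, had 0 counts in CS and 1389 in RA, at least 22.3-fold lower (edgeR adjusted p = 8.57e-05). Siglecf, the lectin used in the AM gate, had 1 count in CS, a pooled ratio of 0.0162 with a counting interval of 0.000411 to 0.0906 (edgeR adjusted p = 0.000158). Gpr155, Cyp51 and Siglece had 2 counts each in CS, with pooled ratios of 0.0578 (0.00699 to 0.21), 0.0669 (0.00808 to 0.243) and 0.1 (0.0121 to 0.364). Krt79 changed by -3.72 ± 0.49, the growth factor receptor Flt1 by -3.29 ± 0.54 and the lipid droplet gene Cidec by -3.15 ± 0.50 (edgeR adjusted p = 0.000309, 0.00366 and 0.00187). Kazald1 changed by -2.67 ± 0.58, the palmitoyltransferase Zdhhc9 by -2.49 ± 0.53 and the transcriptional coactivator Wwtr1 by -2.48 ± 0.55 (edgeR adjusted p = 0.0221, 0.0184 and 0.0255).

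On GRCm38, Ccl7 (ENSMUSG00000035373) and Ccl2 (ENSMUSG00000035385) are neighbouring protein-coding genes on the plus strand of chromosome 11, at 82045712 to 82047525 and 82035571 to 82037453, and Wfdc17 (ENSMUSG00000069792) lies at 83703991 to 83706268 of the same strand. Msr1 (ENSMUSG00000025044) lies on chromosome 8 at 39581685 to 39642673, Spp1 (ENSMUSG00000029304) on chromosome 5 at 104435118 to 104441050, Cd93 (ENSMUSG00000027435) on chromosome 2 at 148436640 to 148443563 and Fabp1 (ENSMUSG00000054422) on chromosome 6 at 71199827 to 71205023. Siglecf (ENSMUSG00000039013) lies on chromosome 7 at 43351341 to 43359531, Ereg (ENSMUSG00000029377) on chromosome 5 at 91074622 to 91093646, and Mmp12 (ENSMUSG00000049723) on chromosome 9 at 7344381 to 7369499.

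Different clusters held most AM-like cells in CS and RA, apart from tomato-positive cells of the myeloid gate after rest, where cluster 8 held most in both. Cluster 9, led by Ear1, Krt79, Cidec, Lepr, Fabp1, Cpne5, Flt1, Siglecf, Krt19 and Epcam, held 70.5% to 86.8% of them in RA libraries apart from the 7 cells of tomato-positive myeloid RA after rest, at 42.9%. In 12-week CS, cluster 7 (led by Igf1, Wfdc21, Ctsk, Car4, Ch25h and Marco) and cluster 8 (led by Wfdc21, Car4, Ltc4s and Chil3, with a median of 1154 UMIs) held 38.1% and 52.4% in tomato-negative and 22.7% and 72.7% in tomato-positive cells. Markers of interstitial macrophages stood higher in CS as well: all 4 measured of 13 listed were positive in both smoke contrasts, at medians of 3.13 at 12 weeks and 5.56 after rest, with 1 and 0 passing (camera adjusted p = 0.0819 and 0.208). The value of 5.56 may rest on floor counts. After rest 1 of 4 complement and 2 of 14 monocyte-derived list members, lists that share genes with these markers, had 0 counts on a side. Leading genes of these clusters that are named here are values within the class, not independent evidence for it.

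Camera called 9 of 21 lists at 12 weeks with the preset correlation, and with an estimated correlation no list call of the 4 contrasts held. In the lipid-laden macrophage list 8 of 19 measured members rose (11 up and 1 down adjusted over the list alone), among them Trem2, a lipid receptor, by 2.61 ± 0.42, and Cd63, a lysosomal tetraspanin, by 2.24 ± 0.31 (edgeR adjusted p = 0.0028 and 0.000416). The list median was 1.06 (camera adjusted p = 1.96e-09, and adjusted p = 0.392 with an estimated correlation). In the lysosome list 24 of 26 members did not pass (7 up adjusted over the list alone), and Ctsd, a lysosomal hydrolase, rose, with a median of 0.57 (camera adjusted p = 2.98e-06, and adjusted p = 0.392 with an estimated correlation). The chemokine list had a median of 0.57, with Ccl2, Ccl7 and Ccl6 up among 12 (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.00153, and adjusted p = 0.402 with an estimated correlation). In the matrix protease list Ctsk and Timp2 rose by 1.77 ± 0.32 and 2.34 ± 0.51 among 15 members (7 up and 1 down adjusted over the list alone), with a median of 0.56 (camera adjusted p = 0.00182, and adjusted p = 0.392 with an estimated correlation). Mmp12, the macrophage elastase, was 4.01 ± 0.92 and did not pass (edgeR adjusted p = 0.136). None of 24 mitochondrial respiration genes passed on its own or adjusted over the list alone. Their median was 0.52 (camera adjusted p = 6e-05, and adjusted p = 0.402 with an estimated correlation).

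The AM identity list fell, with a median of -0.67 and 5 of 24 members down (7 down adjusted over the list alone; camera adjusted p = 1.3e-09, and adjusted p = 0.392 with an estimated correlation). The cholesterol synthesis list fell, with a median of -1.29 (camera adjusted p = 4.02e-06, and adjusted p = 0.392 with an estimated correlation). Its member Cyp51, a lanosterol demethylase, passed among 12 (4 down adjusted over the list alone), while Idi1 at -2.54 did not (edgeR adjusted p = 0.0738). In the fatty acid and PPARγ list, median -0.31, Fabp5 rose and Fabp1, Cidec and Cpt1a fell among 19 members (1 up and 5 down adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.529 with an estimated correlation). Among 20 immediate early genes, median -0.93, Btg2 fell (6 down adjusted over the list alone; camera adjusted p = 1.98e-05, and adjusted p = 0.392 with an estimated correlation).

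The other lists were not called at 12 weeks. Camera adjusted p was 0.0534 for inflammatory mediators (median -0.53, Socs3 up), 0.0943 for NRF2 (0.16; the ferritin genes Ftl1 and Fth1 and Esd up), 0.0943 for complement (-0.45, C5ar1 down) and 0.0943 for glycolysis (0.13, Pgam1 up). It was 0.182 for monocyte-derived macrophages (0.32, Itgam up), 0.334 for iron handling (-0.06), 0.369 for metallothioneins (-0.32), 0.387 for interferon response (0.43), 0.387 for cell cycle (0.90), 0.401 for scavenger receptors (-0.18, Msr1 and Cd68 up), 0.539 for MHC class II (-0.34) and 0.913 for LXR targets (0.09, Ch25h up). For iron handling and scavenger receptors the mean and test were positive against a negative median. For complement the mean was positive, and for LXR targets the test pointed down. Of the aryl hydrocarbon receptor targets, Tiparp was measured, at -0.48 at 12 weeks and -0.76 after rest (edgeR adjusted p = 0.595 and 0.256).

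Scaling by library size alone moved the median of all genes by -0.14 at 12 weeks and gave 131 genes, 54 up and 77 down. The count was 32 without tomato-negative RA at 12 weeks, 355 without tomato-positive CS at 12 weeks, and 216 without tomato-negative CS after rest. It was 35 without cluster 8 and 24 after subtraction of a bounded free-RNA estimate.

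The third comparison asked what remained different in AM-like cells after 8 weeks of rest (2 CS against 2 RA libraries of the myeloid gate). Wfdc17 was up by 5.16 ± 0.41 log2 units (edgeR adjusted p = 1.78e-06), Ccl7 by 6.46 ± 0.73 (edgeR adjusted p = 4.19e-05) and Fabp5, a fatty acid-binding protein, by 3.39 ± 0.31 (edgeR adjusted p = 4.26e-06). Some mitochondrial, lipid-laden and ferritin genes rose, and some MHC class II and immediate early genes fell. None of these list calls held with an estimated correlation, and iron handling was not called. Ereg changed by -4.67 ± 0.59 and Flt1 by -3.64 ± 0.57 (edgeR adjusted p = 0.000279 and 0.00243).

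Of 5535 genes, 299 rose and 152 fell, 444 of them the same way in both tomato fractions. Syngr1 had 1 count in RA, a pooled ratio of 83 with a counting interval of 14.2 to 3350 (edgeR adjusted p = 0.000452). Msr1 rose by 4.02 ± 0.79, Itgam by 3.93 ± 1.02, Igf1 by 3.82 ± 0.53 and the LIM protein gene Crip1 by 3.44 ± 0.56 (edgeR adjusted p = 0.00782, 0.027, 0.000447 and 0.00682). Spag11b rose by 3.39 ± 0.85 (edgeR adjusted p = 0.0328) but was at -0.17 in a fit of the AM-gate libraries. Spp1 rose by 1.93 ± 0.32 and Trem2 by 2.32 ± 0.51 (edgeR adjusted p = 0.00243 and 0.015). Cxcl3, a neutrophil chemokine, had 2 counts in CS, a pooled ratio of 0.0324 (0.00387 to 0.12), as did Trim29 at 0.0654 (0.00772 to 0.248), and the small GTPase gene Rab44 had 3, at 0.0963 (0.0193 to 0.296). The histone acetyltransferase gene Kat6b changed by -3.34 ± 0.64, Lsmem1 by -3.73 ± 0.67, Plxdc2 by -3.14 ± 0.71 and Wwtr1 by -3.07 ± 0.60 (edgeR adjusted p = 0.00782, 0.0042, 0.0152 and 0.00769). Pdk4, an inhibitor of pyruvate dehydrogenase, changed by -3.13 ± 0.60 and the inositol transporter gene Slc5a3 by -3.04 ± 0.78 (edgeR adjusted p = 0.00703 and 0.028). Siglecf changed by -2.11 ± 0.48 and Cidec by -2.36 ± 0.49, while Fabp1 at 0.27 and Krt79 at -1.37 did not pass (edgeR adjusted p = 0.0155, 0.0108, 0.709 and 0.0569). Cluster 8 held 84.0% and 83.5% of tomato-negative and tomato-positive AM-like cells in CS, against 11.2% and 57.1% (4 of 7 cells) in RA.

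Ccl4, Ccl5, Hist1h1e and Ly6c2 also rose, by 5.70 ± 0.51, 4.05 ± 0.44, 4.52 ± 0.69 and 4.44 ± 0.94 (edgeR adjusted p = 3.7e-06, 2.72e-05, 0.00409 and 0.0132), and all 4 are among the 50 genes most specific to NK cell-like cells. NK marker genes rose with them: 3 of 4 measured passed, at a list median of 4.33. In tomato-negative CS after rest NK markers made up 0.981% of AM-like UMIs and Ccl5 stood at 6615.8 CPM, against 487.7 in tomato-negative RA and 2.4 in tomato-positive CS. An NK cell profile that gives this marker share would make up 31.3% of AM-like UMIs there, against at most 2.17% in any other library. This library is among the CS libraries behind every value of this contrast. Ccl4 stood at 1357.3 CPM in tomato-negative CS but also at 499.6 in tomato-positive CS, where NK markers had 0 UMIs. Ly6c2 was at -1.29 with the AM-gate libraries added, -2.31 in those libraries alone, -1.67 without tomato-negative RA after rest and 0.84 without tomato-negative CS after rest.

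The chemokine list had a median of 2.38, with Ccl2, Ccl4, Ccl5, Ccl6 and Ccl7 up and Cxcl3 down among 12 (6 up and 1 down adjusted over the list alone; camera adjusted p = 6.12e-06, and adjusted p = 0.385 with an estimated correlation). In mitochondrial respiration 12 of 24 members rose (14 adjusted over the list alone), such as Cox5a by 1.58 ± 0.33 and Ndufb8 by 1.58 ± 0.36, with a median of 1.12 (camera adjusted p = 2.62e-06, and adjusted p = 0.385 with an estimated correlation). In the lipid-laden list 7 of 19 rose (8 adjusted over the list alone), median 0.79 (camera adjusted p = 1.3e-05, and adjusted p = 0.385 with an estimated correlation). In the NRF2 list 6 of 23 rose (7 adjusted over the list alone), among them Ftl1 by 2.22 ± 0.25, Fth1 by 1.99 ± 0.28 and the biliverdin reductase gene Blvrb by 1.83 ± 0.40. The NRF2 median was 0.28, or -0.16 with library-size scaling alone (camera adjusted p = 0.00106, and adjusted p = 0.385 with an estimated correlation). H2-Aa at -1.85 ± 0.39 and the invariant chain gene Cd74 at -1.38 ± 0.33 fell among 9 MHC class II genes (6 down adjusted over the list alone), median -1.07 (camera adjusted p = 0.00106, and adjusted p = 0.452 with an estimated correlation). Among 20 immediate early genes 6 fell (1 up and 9 down adjusted over the list alone), among them Fos by -1.83 ± 0.30 and Zfp36 by -1.94 ± 0.33, median -0.86 (camera adjusted p = 1.58e-05, and adjusted p = 0.385 with an estimated correlation). The AM identity list had Fabp4 up and Flt1, Cidec, Siglecf and Bhlhe40 down among 24 (2 up and 6 down adjusted over the list alone), median -0.52 (camera adjusted p = 0.0295, and adjusted p = 0.72 with an estimated correlation).

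After rest camera adjusted p was 0.0646 for inflammatory mediators (median -0.74, Osm down), 0.0692 for cholesterol synthesis (-0.46), 0.0775 for matrix proteases (0.69, Ctsk and Cst3 up), 0.107 for interferon response (1.39, Bst2 up), 0.121 for iron handling (0.18; Ftl1 and Fth1 up, Trf down) and 0.167 for cell cycle (0.61, Stmn1 up). It was 0.421 for LXR targets (-0.43), 0.58 for monocyte-derived macrophages (0.99), metallothioneins (0.12) and glycolysis (0.14, Gapdh up), 0.819 for complement (-0.02) and 0.945 for fatty acid targets (0.08), lysosome (0.04) and scavenger receptors (-0.08). Medians and means differed in sign for fatty acid targets, LXR targets, glycolysis, lysosome, complement and scavenger receptors. With library-size scaling alone the lipid-laden median was 0.35, mitochondrial respiration 0.69, chemokines 1.95, MHC class II -1.51, immediate early genes -1.30 and AM identity -0.95. Under it the medians of metallothioneins, iron handling, fatty acid targets, lysosome and glycolysis turned negative, and Bst2, Stmn1, Gapdh and Clec4n lost their calls.

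Library-size scaling moved the median of all genes by -0.42 after rest and gave 681 genes, 128 up and 553 down. The count was 55 without tomato-negative RA after rest, 70 without tomato-positive RA after rest, 163 without tomato-positive CS after rest, and 780 and 810 without tomato-positive and tomato-negative CS at 12 weeks. It was 30 without cluster 8, 9 after subtraction of a bounded free-RNA estimate and 1481 with the AM-gate libraries.

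**Figure D2:**
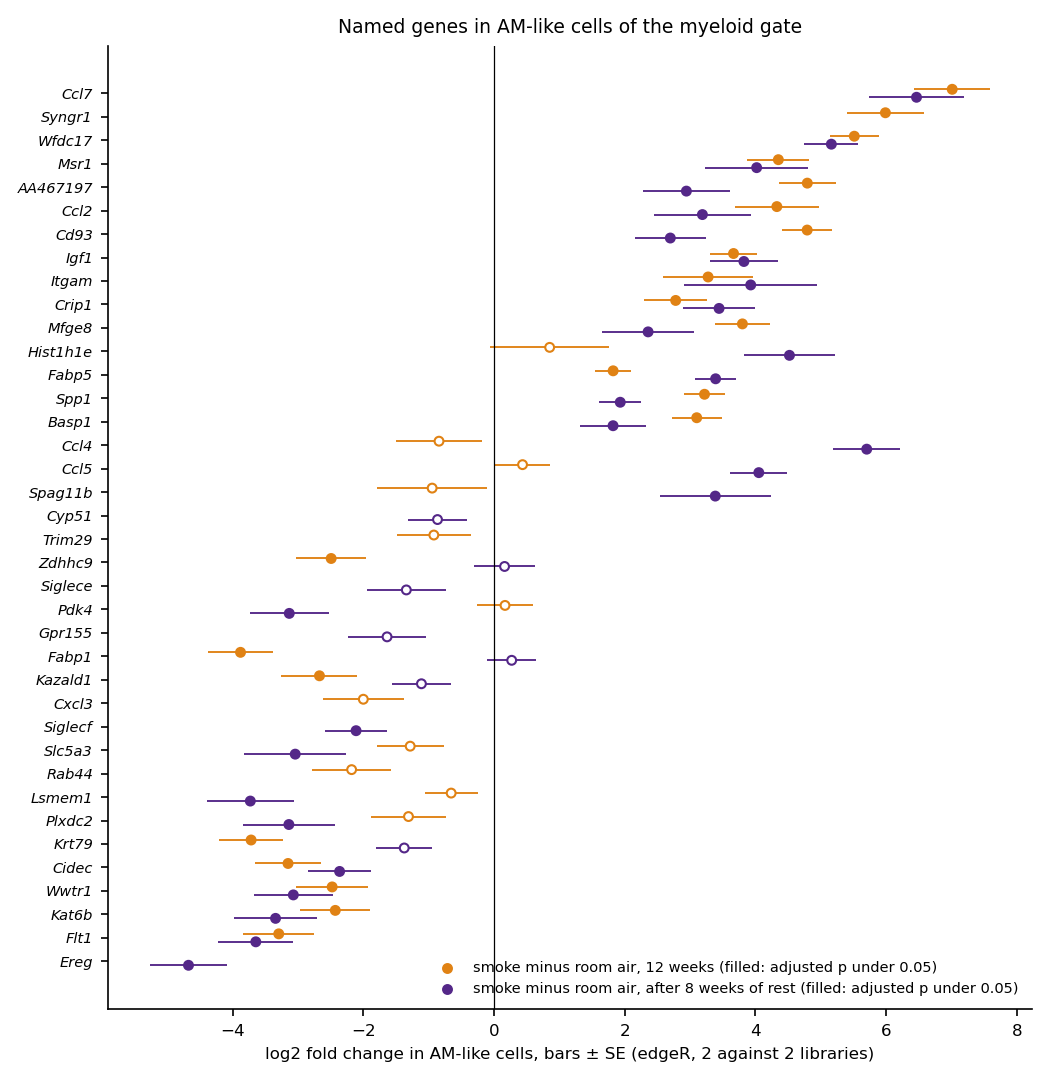
Log2 fold change of CS over RA (horizontal axis, with SE) for named genes in AM-like cells at 12 weeks (orange) and after rest (purple), where filled points have an edgeR adjusted p under 0.05 and values with 3 or fewer counts on a side are left out. Wfdc17 lies at 5.51 and 5.16, and Fabp1 at -3.88 and 0.27.

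**Figure D3:**
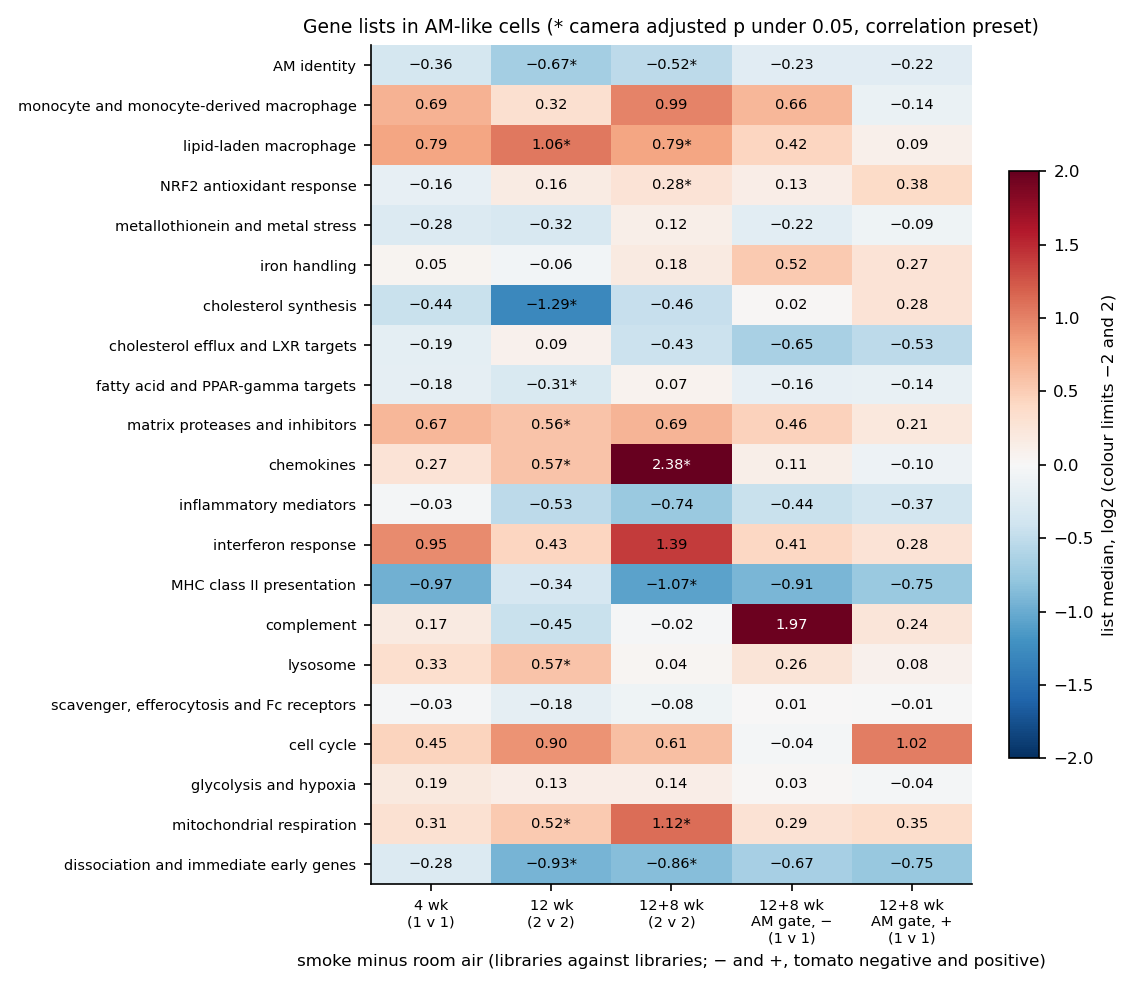
Median log2 change of CS over RA in each gene list (rows) for 5 smoke comparisons of AM-like cells (columns), with a star where camera's adjusted p with the preset correlation was under 0.05, none of which held with an estimated correlation. The medians of MHC class II after rest (-1.07) and mitochondrial respiration (0.52 and 1.12) keep their sign with library-size scaling, while that of NRF2 after rest (0.28) turns to -0.16.

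The difference between both smoke effects was tested directly, as smoke at 12 weeks minus smoke after rest, and 8 genes passed. In RA, AM-like cells made up 8.06% of tomato-negative and 4.47% of tomato-positive cells at 12 weeks, but 1.02% and 0.547% after rest. Neutrophil-like cells were 0% at 12 weeks and 8.52% of tomato-positive RA after rest. The myeloid gate may thus hold different AM-like cells at each time, which this contrast cannot tell apart from a change in the smoke effect. Cxcr4, a chemokine receptor that retains cells in tissue, was higher in this contrast by 2.69 ± 0.51 (edgeR adjusted p = 0.0385), and Fabp1 was at -4.15 ± 0.63 (edgeR adjusted p = 0.00726), lower in CS at 12 weeks and not after rest in this gate. In an added fit of the AM-gate libraries after rest, with a single library per group, Fabp1 was lower in CS, at -0.64. Ccl4 was at -6.54 ± 0.76 and Ccl5 at -3.62 ± 0.59 (edgeR adjusted p = 0.000517 and 0.0107), with the NK genes Gzma and Nkg7 at -3.87 and -3.88. The ribosomal RNA-derived transcripts AY036118 at -3.1 and Gm42418 at -2.22 complete the set. Without the NK cell profile 5 genes passed, and 0 passed without cluster 8 (196 at an unadjusted p under 0.05) or after the bounded free-RNA subtraction (201), where DESeq2 on the unsubtracted counts gave 12. Leaving out a library of 12 weeks gave 57 without tomato-positive CS, 19 without tomato-negative CS and 13 without tomato-positive RA. Leaving out a library after rest gave 16 and 14 without tomato-positive and tomato-negative CS, and 3 without tomato-negative RA.

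Lists for lysosome and MHC class II stood higher in this contrast, at medians of 0.55 and 0.53 (camera adjusted p = 0.000234 and 0.00562, and adjusted p = 0.683 for both with an estimated correlation), with 0 of 26 and 0 of 9 members passing. AM identity at -0.28, fatty acid targets at -0.56 and chemokines at -0.58 stood lower (camera adjusted p = 0.00562, 0.00562 and 0.0104, and adjusted p = 0.719, 0.683 and 0.683 with an estimated correlation), with Fabp1 passing in the first pair and Ccl4 and Ccl5 in the last. Adjusted over the list alone 4, 2 and 2 were down, and 1 fatty acid gene was up. NRF2 at -0.45 and mitochondrial respiration at -0.35 had no passing member (1 down adjusted over the list alone in the latter; camera adjusted p = 0.0357 and 0.044, and adjusted p = 0.683 and 0.719 with an estimated correlation). Library-size scaling moved the median of all genes by 0.28 and that of AM identity to 0.02. It ended the calls of NRF2 at -0.17 and mitochondrial respiration at -0.07 (camera adjusted p = 0.0711 and 0.127). Medians of fatty acid targets, chemokines, MHC class II and lysosome were -0.23, -0.33, 0.81 and 0.84 under it.

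The tomato contrast asked how tomato-positive AM-like cells differed from tomato-negative ones, across all 4 exposure groups (4 against 4 libraries). Classical monocyte-like cells made up 1.98% to 2.98% of the tomato-negative myeloid libraries. A lack of tomato may therefore not mean a lack of monocyte-progenitor history, in AM-like or in monocyte-like cells. Of 5535 genes 0 rose and 8 fell in tomato-positive cells, and each fell in all 4 pairs. Ccl7 changed by -4.83 ± 0.49 (edgeR adjusted p = 1.92e-05) and Vps37b, an endosomal sorting gene, by -4.35 ± 0.49 (edgeR adjusted p = 0.000112). Ccl5 had 2 counts in tomato-positive cells, a pooled ratio of 0.00281 (0.00034 to 0.0101), and Gzmb 1 count, a ratio of 0.0215 (0.000542 to 0.121). Ccl4 was at -1.91 ± 0.36 (edgeR adjusted p = 0.0314), though its pooled ratio of 1.43 lay the other way, and Gzma, Nkg7 and Prf1 completed the set. Vps37b, Gzmb, Ccl4 and Ccl5 are also among the most NK-specific genes, and NK cell-like cells were nearly absent from the tomato-positive libraries.

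The chemokine list stood lower in tomato-positive cells at a median of -0.94, with Ccl4, Ccl5 and Ccl7 down among 12 (1 up and 4 down adjusted over the list alone; camera adjusted p = 4.16e-15, and adjusted p = 0.212 with an estimated correlation). The cell cycle list had a median of -1.24 with none of 7 passing (5 down adjusted over the list alone; camera adjusted p = 3.16e-09, and adjusted p = 0.712 with an estimated correlation). Ccnb2 was at -2.12 and Mki67 at -1.68. The proliferating cluster 23 held 9.52% and 4.95% of tomato-negative AM-like cells in CS and RA at 12 weeks and 2% and 14.3% after rest, against 0% and 2.5%, and 4.13% and 0%, of tomato-positive ones. AM identity at 0.44, scavenger receptors at 0.30 and fatty acid targets at 0.20 stood higher with no passing member (camera adjusted p = 5.98e-08, 0.008 and 0.00191, and adjusted p = 0.823 for each with an estimated correlation). These rises did not recur in the AM gate after rest, where tomato fractions were compared without a test. Medians there in CS and RA were -0.045 and -0.07 for AM identity, -0.021 and 0.005 for scavenger receptors and -0.037 and -0.057 for fatty acid targets. The count was 1 without the NK cell profile, 3 with DESeq2 and 0 after bounded free-RNA subtraction (150 at an unadjusted p under 0.05). It was 20 with doublets kept, 89 without the count filter and 18 in the AM-gate libraries, which share none of the 8. Each left-out library raised the count. At 12 weeks it went to 52 without either CS library, 42 without tomato-negative RA and 41 without tomato-positive RA. After rest it went to 23, 21, 18 and 27 without tomato-negative CS and RA and tomato-positive CS and RA.

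At 4 weeks CS and RA were compared to ask how AM-like cells differed early in exposure. This is 1 library against 1, with 60 and 1210 AM-like cells and no test. Mmp12, the macrophage elastase, stood 19.7-fold higher in CS (counting interval 16.2 to 23.8), at 361 against 18.3 CPM. Wfdc17 was 8.6-fold higher (7.9 to 9.35), Cd93 16.9-fold (13.5 to 21.2), Syngr1 80.3-fold (42.4 to 159) and Msr1 12.8-fold (9.7 to 16.7). Syngr1 is also a leading gene of the Inhba-Gpnmb cluster, which made up 51.7% of this CS library. The planned free-RNA estimate for the AM-like cells of this CS library was 233%, with Wfdc21, a leading gene of AM-like clusters, among its markers. Without Wfdc21 the estimate was 29.99%, just under the bound. Its subtraction took the log2 ratio of Syngr1 from 3.66 to 3.1. Fabp1 was 8.2-fold lower (5.67 to 12.3). The log2 ratios of CPM + 5 were 3.71 for Fstl1, a secreted follistatin-like protein, 3.46 for Ptgs1, the constitutive cyclooxygenase, 3.40 for Fkbp11, 3.14 for Itgam, 3.09 for Zranb3, 2.98 for Mfge8 and 2.76 for the prostacyclin receptor gene Ptgir. They were -3.23 for the peroxisomal thiolase gene Acaa1b, -2.47 for Flt1 and Cidec, -2.45 for Syne2, -2.44 for Krt79, -2.43 for Cxcl3 and -2.12 for Siglecf. Cpne5, Gpr155 and Rab44 had 3 counts each in CS, 29.3-fold (10 to 142), 10.6-fold (3.62 to 51.5) and 9.23-fold (3.15 to 44.8) lower. Tanc2 had 2, 12.2-fold lower (3.37 to 101).

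Percentiles place each list's median among 10000 random lists of like expression. Lipid-laden (0.79; Trem2 2.62, Spp1 2.5), matrix proteases (0.67) and lysosome (0.33; Lgmn 1.52) stood at percentile 100, with 14 of 20, 13 of 17 and 22 of 26 measured members higher in CS. So did cell cycle (0.45; Mki67 1.32 but Top2a -1.15) and mitochondrial respiration (0.31; Cycs 0.56 but Ndufa4 -0.57), with 15 of 19 and 21 of 24 members higher. The monocyte-derived list (0.69, with Apoe at 2.04) and the interferon response list (0.95, with Rtp4 at 1.98) also stood at 100. Both medians were 0.0 after bounded free-RNA subtraction. It removes a profile of the cells outside the AM-like class, other macrophages and monocytes among them, and sets negative counts to 0. List members can thereby reach 0 in both libraries, so this value cannot tell whether their difference between CS and RA remains. MHC class II (-0.97; Cd74 -1.22, H2-Aa -1.16) stood at percentile 0, and AM identity (-0.36) at 0.2. Cholesterol synthesis (-0.44; Idi1 -1.80) stood at 0.7 with 17 of 20 members lower, and immediate early genes (-0.28; Fos -1.36) at 1.3. Chemokines (0.27; Ccl17 2.71, Ccl9 2.45, Ccl2 2.23) stood at 99.4 with 8 members higher and 8 lower. Fatty acid targets (-0.18), NRF2 (-0.16), metallothioneins (-0.28), LXR targets (-0.19), inflammatory mediators (-0.03), scavenger receptors (-0.03), iron handling (0.05), complement (0.17; C3ar1 2.59) and glycolysis (0.19) stood between percentiles 7.7 and 97. Of the AM-like cells in CS, 36.7% were in the proliferating cluster 23 (led by Top2a and Mki67), 38.3% in cluster 8 and 21.7% in cluster 7.

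In the AM gate after rest, CS and RA were compared within each tomato fraction, to ask what remained in sorted AMs of either fraction. AM-like cells numbered 4233 against 234 in tomato-negative and 4390 against 132 in tomato-positive libraries. Mmp12 was 98.3-fold higher in tomato-negative CS (78.4 to 125; 749 against 7.6 CPM) and 64.8-fold in tomato-positive CS (45.7 to 95.5; 492 against 7.58 CPM). Wfdc17 was 31-fold (28 to 34.4) and 22.2-fold higher, Cd93 15-fold and 26.3-fold, and Msr1 23.1-fold and 19-fold. C1qa, the first component of the classical complement pathway, had 0 counts in both RA libraries and was at least 327-fold higher in tomato-negative and at least 28.5-fold higher in tomato-positive CS. It also marks interstitial macrophage-like cells, which made up 0.753% and 0.408% of these CS libraries and 0 cells in RA. The planned free-RNA estimates, whose markers include Wfdc21, were 48.1% and 168% for AM-like cells of these CS libraries. Without Wfdc21, a leading gene of AM-like clusters, they were 9.56% and the bound of 30%. C1qa from other cells is therefore not excluded. Apoe, an apolipoprotein that exports lipid, was 10.2-fold higher in tomato-negative CS, at 292 against 28.8 CPM, but lower in tomato-positive CS, at 96 against 141.

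C1qc, with 0 counts in RA, was at least 201-fold and 15.9-fold higher. Further log2 ratios of CPM + 5 in tomato-negative cells were 3.77 for AA467197, 2.81 for Pla2g2d, 2.70 for Ptgir, -3.06 for Adgrl3, -2.32 for Flt1, -2.22 for Plekhg2, -2.14 for Nme2, -2.04 for Ereg, -1.95 for Hr, -1.90 for Wwtr1 and -1.89 for Kat6b. In tomato-positive cells they were 3.00 for Ch25h, 2.72 for Top2a, 2.59 for Pclaf, 2.55 for Rrm2, 2.34 for Ptgir, 2.23 for Plpp3, -3.23 for Ereg, -3.19 for Adgrl3, -2.86 for Tcim, -2.56 for Egr1, -2.43 for Flt1, -2.06 for Ifitm3 and -2.04 for Pdk4. Siglecf, on which the gate selects, was at -1.74 and -1.76. Cluster 7 held 74.7% of tomato-negative CS cells and cluster 8 held 59.2% of tomato-positive CS cells, and median UMIs per kept cell were 17666.5 and 1895 in CS against 44137 and 35166 in RA.

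In tomato-negative and tomato-positive cells, MHC class II had medians of -0.91 and -0.75 (percentile 0 in both), immediate early genes -0.67 and -0.75 (percentile 0, with 20 of 21 members lower in each) and mitochondrial respiration 0.29 and 0.35 (percentile 100). Complement stood at 1.97 (percentile 100) and 0.24 (97.9), the monocyte-derived list at 0.66 (100) and -0.14 (45.4), and lipid-laden at 0.42 (100) and 0.09 (86.3). Cell cycle stood at -0.04 (78.9) and 1.02 (100), with 20 of 20 members higher in the latter. In the tomato-positive RA library behind that value, the proliferating cluster 23 held 7 of 132 AM-like cells (5.3%), against 8.93% in CS. Few cycling cells therefore lie behind its RA side. AM identity was at -0.23 (4.3) and -0.22 (4.0), NRF2 at 0.13 (98.8) and 0.38 (100), interferon response at 0.41 (100) and 0.28 (99.8) and LXR targets at -0.65 (0) and -0.53 (0.2). Cholesterol synthesis, which had negative medians in the myeloid gate at 4 weeks, at 12 weeks and after rest (-0.46), stood at 0.02 (95.5) and 0.28 (100, with 15 of 19 members higher), and chemokines at 0.11 (96.3) and -0.10 (35.3). Matrix proteases were at 0.46 (100) and 0.21 (99.2), iron handling at 0.52 (100) and 0.27 (95.5), lysosome at 0.26 (100) and 0.08 (96.7) and inflammatory mediators at -0.44 (0.1) and -0.37 (1.3).

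Of the genes called in the myeloid gate, those with a mean of at least 5 CPM in the AM gate were compared in direction. For smoke after rest 382 of 446 went the same way in both tomato fractions (85.7%, against 57.5% of genes not called), 233 of 294 that rose and 149 of 152 that fell. Genes called for smoke at 12 weeks were set against the same AM-gate libraries, which are all after rest. Of these genes 89 of 96 went the same way in both tomato fractions, 52 of 57 that rose and 37 of 39 that fell. The share among genes not called was not taken for that contrast.

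Genes lower in tomato-positive than tomato-negative AM-gate cells in CS included C1qa, 4.76-fold lower (4.36 to 5.22), C1qc, 5.25-fold, C1qb, 3.6-fold, Apoe, 3.05-fold, Mfge8, 2.84-fold, and the scavenger receptor gene Marco, 2.05-fold lower. Igkc was at a log2 ratio of -2.73, Ecm1 at -1.29, Vcam1 at -1.19, Bcl2a1d at 0.82 and Tmsb10 at 0.79. Cluster 8, of low UMI counts, held 59.2% of tomato-positive and 4.82% of tomato-negative AM-like cells in CS. Interstitial macrophage-like cells were 0.408% and 0.753% of these libraries. A cluster of 19 cells with C1qa, C1qb, C1qc and Apoe among its leading genes, 94.7% from tomato-positive CS, was not counted as AM-like. These differences in makeup were not told apart from a difference by tomato. Complement (-0.55), monocyte-derived (-0.48), chemokine (-0.29) and matrix protease lists (-0.24) stood at percentile 0, and cell cycle at 0.14 and percentile 100, with 18 of 20 members higher. In RA, Ly6c2 and F13a1, genes of classical monocytes, were at least 101-fold and 60.1-fold higher in tomato-positive cells. That library held 6 nonclassical monocyte-like cells of 144 (4.17%), against 0 of 240 in tomato-negative RA. Its planned free-RNA estimate was 21.4%, or 10.8% without the marker Wfdc21. In the same comparison Ifitm3 had 3 counts in tomato-negative cells and was 269-fold higher (91.1 to 1310), Apoe was 4.91-fold higher and Top2a 8.9-fold lower. The monocyte-derived list stood at 0.26 in RA (percentile 100) and cell cycle at -0.91 (percentile 0, with 20 of 20 members lower). Cluster 23 held 7 of 132 tomato-positive cells (5.3%) and 12 of 234 tomato-negative ones (5.13%), so few cycling cells lie behind that value, at much the same share in both.

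Monocyte-like cells were compared in the same 8 libraries to ask whether smoke and tomato effects extended beyond AMs. In classical monocyte-like cells at 12 weeks 8 genes rose and 6 fell of 9689, led by the heat shock genes Hspa1b at 2.64 ± 0.20 and Hspa1a at 2.27 ± 0.14 and the immediate early genes Egr1 at 0.98 ± 0.15 and Jun at 0.94 ± 0.13 (edgeR adjusted p = 0.000189, 8.59e-08, 0.00414 and 0.00237). After rest 1108 rose and 975 fell, among them Spp1 by 2.18 ± 0.50, the interferon-induced Isg15 by 1.03 ± 0.11 and the respiratory chain gene Cox5a by 0.70 ± 0.12 (edgeR adjusted p = 0.00671, 6.16e-05 and 0.0011). In nonclassical monocyte-like cells 12 rose and 19 fell of 9482 at 12 weeks, and 677 rose and 450 fell after rest. By tomato, 377 genes rose and 693 fell in classical and 102 rose and 266 fell in nonclassical cells. MHC class II genes were lower in tomato-positive classical monocyte-like cells, H2-Aa by -1.42 ± 0.16, H2-Eb1 by -1.81 ± 0.29 and Cd74 by -1.20 ± 0.15 (edgeR adjusted p = 0.000781, 0.0224 and 0.000195), and the chitinase-like gene Chil3 was higher by 0.97 ± 0.10 (edgeR adjusted p = 4.48e-05). H2-Eb1 and Cd74 also lead a cluster with 9 cDC2 markers raised. The cDC2-like share was 3.36% to 6.03% in tomato-negative and 0.95% to 1.88% in tomato-positive libraries. Captured RNA was not subtracted for monocyte-like cells, so it was not told apart from a difference of the monocytes. Direct tests of smoke at 12 weeks minus smoke after rest called 585 and 411 genes.

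In classical monocyte-like cells camera called immediate early genes at 12 weeks at a median of 0.11 with 4 up (camera adjusted p = 8.79e-15, and adjusted p = 0.361 with an estimated correlation). MHC class II at 0.32 and interferon response at -0.29 were called too (camera adjusted p = 0.00139 and 0.00324, and adjusted p = 0.448 and 0.361 with an estimated correlation). So were AM identity at 0.10, scavenger receptors at 0.16 and glycolysis at -0.09, each lost with an estimated correlation. After rest it called mitochondrial respiration at 0.44 with 13 up and 3 down of 24 (camera adjusted p = 0.000984, and adjusted p = 0.859 with an estimated correlation) and the lipid-laden list at 0.41 with 8 up and 1 down of 20 (camera adjusted p = 0.0282, and adjusted p = 0.859 with an estimated correlation). In tomato-positive classical cells it called MHC class II at -0.98 with 1 up and 6 down of 11 (camera adjusted p = 4.55e-11, and adjusted p = 0.56 with an estimated correlation) and mitochondrial respiration at -0.33 with 13 of 24 down (camera adjusted p = 6.97e-08, and adjusted p = 0.56 with an estimated correlation). In nonclassical cells interferon response stood at -0.50 at 12 weeks with Rsad2 down among 20 (camera adjusted p = 4.02e-11, and adjusted p = 0.559 with an estimated correlation), and mitochondrial respiration at 0.46 after rest with 14 of 24 up (camera adjusted p = 4.99e-06, and adjusted p = 0.622 with an estimated correlation).

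With library-size scaling the median of all genes moved by -0.25 in classical and -0.26 in nonclassical monocyte-like cells after rest, where 384 genes rose and 2125 fell in the former and 282 rose and 1679 fell in the latter. By tomato 562 rose and 359 fell and 206 rose and 195 fell. The 12-week minus rest contrast gave 599 up and 102 down and 629 up and 108 down against 245 up and 340 down and 127 up and 284 down. List medians after rest were 0.21 for mitochondrial respiration and 0.18 for the lipid-laden list in classical cells, and 0.23 for mitochondrial respiration in nonclassical cells. Leaving out a library moved the rest counts to between 322, without tomato-positive CS after rest, and 2777, without tomato-negative CS at 12 weeks, in classical cells. In nonclassical cells the range was from 66, without tomato-positive RA after rest, to 1576, without tomato-negative CS at 12 weeks.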

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

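The tests of NK marker levels in the AM gate, of direction in the AM gate, and the 3 tests on the 4-week AM-like share were chosen after those results were seen, while the other tests of this part were written down first.

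In AM-like cells 8 genes differed between smoke at 12 weeks and smoke after rest, by the test of the difference itself. The myeloid gate may hold different AM-like cells at each time. The log2 differences (12 weeks minus rest) were 2.69 for Cxcr4, -4.15 for Fabp1, -3.88 for Nkg7, -3.62 for Ccl5, -6.54 for Ccl4, -3.87 for Gzma, -2.22 for Gm42418 and -3.10 for AY036118. By the same test with camera's preset correlation, list medians differed by -0.28 for AM identity, -0.45 for NRF2, -0.56 for fatty acid targets, -0.58 for chemokines, 0.53 for MHC class II, 0.55 for lysosome and -0.35 for mitochondrial respiration, and none of the 7 held with an estimated correlation (camera adjusted p between 0.683 and 0.719). The same contrast called 585 genes in classical and 411 in nonclassical monocyte-like cells. After rest the AM-like share of the myeloid gate differed between CS and RA by -0.81 percentage points in tomato-negative and by 0.96 in tomato-positive cells, and the difference between those was not tested. In the AM gate the tomato contrast of the monocyte-derived list was -0.48 in CS and 0.26 in RA, and that of the cell cycle list 0.14 in CS and -0.91 in RA, likewise untested.

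The NK marker genes, with Nkg7 and Gzma above among them, made up 0.981% of AM-like UMIs in tomato-negative CS after rest. An NK cell profile that gives this share would make up 31.3% of those UMIs. Ccl4 and Ccl5 are NK-specific genes outside these markers. Of 50 NK-specific genes that were not used as markers, 94% lay within 2-fold of their median ratio between AM-like and NK cell-like cells, 27.6% (quartiles 23.5 to 31.6), as capture of NK cell RNA with these cells requires. Against expression of these genes by tomato-negative AM-like cells after smoke and rest, their NK marker share in the AM gate was 0.00703% of that in the myeloid gate. NK RNA captured with AM-like cells, free or from doublets, is therefore a candidate explanation for Ccl5, Nkg7 and Gzma, and it bears on the tomato contrast because tomato-positive libraries hold few NK cells. It does not account for all of Ccl4, of whose 425 counts in CS after rest 210 were in tomato-positive CS, where NK markers had 0 UMIs. Ccl5 was also higher in CS in the fit of the AM-gate libraries, by 2.42. NK markers were 0.0001% of AM-like UMIs in each CS library there, so NK RNA may not account for all of Ccl5 either. Fabp1 and Cxcr4 are not NK-specific genes. They, that part of Ccl4 and the rise of Ccl5 in the AM gate stay open.

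More genes were called for smoke after rest than at 12 weeks, 451 against 97. This order depends on the processing: it was 9 against 24 with bounded free-RNA subtraction and 30 against 35 without cluster 8, and the count after rest was 55 or 70 without either RA library after rest. Across the called genes, changes after rest in AM-like and classical monocyte-like cells correlated at r = 0.696 (genes are not independent replicates), against 0.295 at 12 weeks, consistent with a shift of whole CS libraries after rest that reaches several cell classes. NK RNA is argued against as the whole cause, since 404 genes passed with the NK profile subtracted. Of the called genes measured in the AM gate 85.7% went the same way there in both tomato fractions, which a smoke difference carried by AM-like cells needs, but those libraries may share mice or processing days with the myeloid-gate libraries. A library-wide shift and a smoke difference both met what they need and stay open together, and the biological part is untested.

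The AM-like share at 4 weeks was lower in CS than in RA. Dilution by other cells alone is argued against, since the fall was 4.34 times that of NK cell-like cells (3.31 to 5.69). With the CS minimum of 1023 UMIs applied to RA, 14.1% of RA cells were AM-like (13.4 to 14.9), against 0.55% in CS. This cannot decide whether AM-like cells in CS fell below that minimum. In RA 86.8% of AM-like cells were in cluster 9, whose median of 15038 UMIs lies far above it. In CS 38.3% were in cluster 8, whose median of 1154 UMIs lies close to it. Loss to the minimum and loss before counting both stay open. AM-like cells could have moved into the Inhba-Gpnmb cluster: across 3834 genes with its 100 leading genes left out, its profile correlated with AM-like cells at rho = 0.737 (0.718 to 0.758), with interstitial macrophage-like cells at 0.790 (0.774 to 0.807) and with classical monocyte-like cells at 0.742 (0.724 to 0.759). None of the AM markers was raised over other cells in that cluster, against 7 interstitial macrophage markers. Those other cells include AM-like cells, so AM markers could be present in the cluster without being raised. By tomato it made up 18.6% of tomato-positive and 4.07% of tomato-negative CS cells at 12 weeks. These values do not settle its origin, and an effect of smoke on the number of AMs stays open and untested.

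For the tomato contrast the 8 splits of the tomato label within exposure groups are too few for a share under 0.05. The real split called 8 genes in AM-like cells, 1070 in classical and 368 in nonclassical monocyte-like cells, the highest other split called 2, 2 and 6, and 1 of 8 splits in each class, the real one, reached the real count.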

How the results depend on the processing

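The bounded free-RNA estimate, the NK profile, the fit without cluster 8, the fits of 4 libraries, the count of the Inhba-Gpnmb cluster as AM-like and the monocyte alternatives were chosen after the data were seen. No paired analysis was possible because every group has replicate 1 only, though the fit takes the tomato contrast within exposure groups. The planned free-RNA subtraction was not run as planned, since its estimate reached 100% or more in 5 libraries; Wfdc21 was left out of its markers and the share was held at 30%. A lone library left in an arm is assumed to vary like the others. The cause was not tested except where a setting's construction shows it (fewer cells or genes, or other libraries). Depth limits the 7 AM-like cells and 66180 UMIs of tomato-positive RA after rest, and 2-fold changes, of which 11.9% were recovered in AM-like cells at 12 weeks and 10.4% in nonclassical monocyte-like cells after rest in simulated data.

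For smoke at 12 weeks (97 genes) the count was 216 without the count filter, 187 with the AM-gate libraries, 180 in the 4 libraries of 12 weeks, 24 with bounded free-RNA subtraction, 35 without cluster 8 (3749 genes tested), and between 32 (without tomato-negative RA at 12 weeks) and 355 (without tomato-positive CS at 12 weeks), with 216 without tomato-negative CS after rest. DESeq2 gave 72. For smoke after rest (451) it was 681 with library-size scaling, 1481 with the AM-gate libraries, 9 with bounded free-RNA subtraction, 30 without cluster 8, 3568 in the AM-gate libraries alone (11905 genes tested; 342 shared, 336 in the same direction), and between 55 (without tomato-negative RA after rest) and 810 (without tomato-negative CS at 12 weeks), with 780 without tomato-positive CS at 12 weeks, 163 and 70 without tomato-positive CS and RA after rest. DESeq2 gave 499.

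For 12 weeks minus rest (8) it was 19 without the count filter, 3 without the cell cycle cluster, 1 with the AM-gate libraries, 5 with the NK profile subtracted, 0 in edgeR with bounded free-RNA subtraction or without cluster 8 (201 and 196 at an unadjusted p under 0.05; DESeq2 was run on the unsubtracted counts alone, with 12), and between 3 (without tomato-negative RA after rest) and 57 (without tomato-positive CS at 12 weeks), with 19 and 13 without tomato-negative CS and tomato-positive RA at 12 weeks and 14 and 16 without tomato-negative and tomato-positive CS after rest. For tomato (8) it was 3 with DESeq2, 89 without the count filter, 15 at a mean CPM of at least 30, 20 with doublets kept, 0 in edgeR with bounded free-RNA subtraction (150 at an unadjusted p under 0.05), 1 with the NK profile subtracted, 18 in the AM-gate libraries, and between 18 (without tomato-positive CS after rest) and 52 (without either CS library of 12 weeks), with 41, 42, 27, 21 and 23 without tomato-positive and tomato-negative RA at 12 weeks, tomato-positive and tomato-negative RA and tomato-negative CS after rest.

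Camera called 9, 7, 7 and 5 lists in these contrasts, 0 in each with an estimated correlation, and 14, 3 and 9 for smoke at 12 weeks, the difference and tomato with bounded free-RNA subtraction, where the MHC class II difference reversed (adjusted p = 0.665). Genes that reversed were Spag11b (-0.17 in the AM-gate libraries) and Ly6c2 (-1.29 with them and -2.31 in them alone, between -1.67 and 5.02 with a library left out) for smoke after rest, and Ccl5 (0.13 in the AM-gate libraries) and Ccl4 (0.009 with them and 1.07 in them alone) for tomato. At 4 weeks the monocyte-derived and interferon list medians were 0.0 with bounded free-RNA subtraction, which can set members to 0 in both libraries. The AM identity list in tomato-negative AM-gate cells was -0.17 with stricter cell filters, against -0.23.

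With the Inhba-Gpnmb cluster counted as AM-like, the AM-like share in CS minus RA was 37.78 points at 4 weeks and 14.5 at 12 weeks in tomato-positive cells, both reversed, and -3.82 at 12 weeks in tomato-negative and 1.89 after rest in tomato-positive cells. DESeq2 called 881, 235 and 542 genes in classical monocyte-like cells for smoke after rest, the difference and tomato, and 8, 330, 85 and 168 in nonclassical cells for the 4 contrasts.

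Leaving out a library gave, in classical cells, 6 (tomato-negative RA at 12 weeks) to 40 (tomato-positive CS at 12 weeks) for smoke at 12 weeks, 322 to 2777 after rest, 37 (tomato-positive RA at 12 weeks) to 1284 (tomato-negative CS at 12 weeks) for the difference, and 196 (tomato-negative RA at 12 weeks) to 954 (tomato-negative CS at 12 weeks) for tomato. In nonclassical cells it gave 7 (tomato-positive RA at 12 weeks) to 67 (tomato-negative CS at 12 weeks), 66 to 1576, 23 (tomato-positive RA at 12 weeks) to 793 (tomato-negative CS at 12 weeks) and 107 (tomato-positive RA after rest) to 370 (tomato-negative CS after rest). The library left out at each end of the counts after rest was tomato-positive CS after rest and tomato-negative CS at 12 weeks in classical cells, and tomato-positive RA after rest and tomato-negative CS at 12 weeks in nonclassical cells. Other values that moved by over 1.5 times in classical cells were 25, 7, 28 and 27 for smoke at 12 weeks (without tomato-negative CS and tomato-positive RA at 12 weeks, and tomato-negative and tomato-positive CS after rest), 591 and 360 after rest (tomato-negative and tomato-positive RA after rest), 81, 81, 75, 88 and 57 for the difference (tomato-positive CS and tomato-negative RA at 12 weeks, and tomato-negative RA, tomato-positive CS and tomato-positive RA after rest), and 199, 606 and 568 for tomato (tomato-positive RA at 12 weeks, tomato-negative and tomato-positive RA after rest). In nonclassical cells they were 50 and 47 (tomato-negative CS and RA after rest), 712 and 83 (tomato-negative RA and tomato-positive CS after rest), 90, 28 and 30 (tomato-positive CS at 12 weeks, tomato-positive CS and RA after rest) and 225, 109 and 203 (tomato-positive CS and RA at 12 weeks, tomato-negative RA after rest).

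Of the remaining comparisons, single genes in the 8-library fit kept direction and side of the threshold in 1520, lost their call in 364 and reversed in 7; list calls did so in 47, 36 and 1. Values between single libraries stayed within their counting interval in 246 and moved in 156 for genes, and in 301 and 43 for lists, with 2 reversed; other shares stayed in 207 and moved in 9.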

Other observations

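No hypothesis is weighed in this part, which gives cell shares not yet given and further genes and lists from the tests of monocyte-like cells. At 4 weeks plasma cell-like cells made up 0.798% of the myeloid gate in CS (0.639 to 0.983) and 0.069% in RA (0.025 to 0.151). A cluster led by the interferon-induced genes Rsad2, Cxcl10 and Ifit3 made up 4.90% in CS and 1.58% in RA at 4 weeks, but 1.70% and 3.02% in tomato-positive cells at 12 weeks and 2.62% and 4.46% after rest. A proliferating cluster led by Pclaf, Ube2c, Birc5 and Mki67 made up 6.14% in CS and 0.45% in RA at 4 weeks. Nonclassical monocyte-like cells were 3.30% in CS and 11.6% in RA at 4 weeks. Among tomato-positive cells they were 41.8% and 47.0% at 12 weeks and 25.4% and 37.7% after rest. Among tomato-negative cells they were 2.04% and 1.94%, and 1.09% and 1.64%. cDC2-like cells were 1.88% in CS and 2.56% in RA at 4 weeks, but 6.03% and 3.79% among tomato-negative cells at 12 weeks, and 4.74% and 3.36% after rest; cDC1-like cells were 2.02% and 1.30% at 4 weeks, then 3.21% and 2.36%, and 2.99% and 1.76%. Basophil-like cells, which descend from the same progenitors that tomato marks, made up 5.64% to 6.4% of the 4 tomato-positive myeloid libraries and under 0.45% of the tomato-negative ones. Neutrophil-like cells appeared in tomato-positive myeloid cells after rest, at 12.6% in CS (11.8 to 13.3) and 8.52% in RA (7.05 to 10.2), and at 0 cells in the other myeloid-gate libraries.

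In tomato-positive classical monocyte-like cells the chemokine list stood lower, at a median of -0.33 with 3 of 14 down (camera adjusted p = 7.04e-08, and adjusted p = 0.204 with an estimated correlation), among them Ccl2 at -0.47 ± 0.10 (edgeR adjusted p = 0.00785), and inflammatory mediators stood higher at 0.24 with 4 up and 1 down (camera adjusted p = 0.0403, and adjusted p = 0.566 with an estimated correlation). In nonclassical cells Chil3 was higher in tomato-positive cells by 1.76 ± 0.15 (edgeR adjusted p = 1.11e-11), and MHC class II stood at -0.85 with 1 of 10 down (camera adjusted p = 4.72e-06, and adjusted p = 0.527 with an estimated correlation). For smoke at 12 weeks minus smoke after rest in classical cells, Hspa1a was at 2.20 ± 0.19, the chemokine gene Ccl3 at 1.55 ± 0.16 and Isg15 at -1.33 ± 0.17 (edgeR adjusted p = 1.96e-05, 9.91e-05 and 0.000547). After rest Fabp5 rose by 0.79 ± 0.16 and Cox5a by 0.66 ± 0.12 in nonclassical cells (edgeR adjusted p = 0.000849 and 0.000157).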
